A study of Arabidopsis thaliana with 6 samples.

How the data were processed

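The samples were 6 libraries from whole 2-week-old seedlings, 3 labelled wild type and 3 labelled NCBP mutant. Per the labels' protocols, plants were grown at 22 °C with 16 hours of light and 8 hours of dark, seedlings were ground in liquid nitrogen, total RNA was taken with a plant RNA kit, and libraries followed a standard Illumina protocol. Selection of mRNA, strandedness, read length and depth are not given in the sources used here.

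The values were FPKM as deposited by the authors in a single table of 22426 loci: 22107 nuclear loci, 32 plastid loci, 60 mitochondrial loci and 227 loci that the authors added under their own names. HISAT2 is named in the submitters' processing notes, without a version. The program that made the FPKM, the genome build and the annotation are not given in the sources used here. The FPKM sums of the libraries lay between 970383 and 1040255, and between 1127 and 1345 loci per library were listed at 0, where a 0 can also be a failed estimate. Some values above 0 are far below what 1 read could give, between 42 and 46 per library under 0.001, so the values are estimates that split reads and not whole-read counts, and no count test was used. FPKM divides by the library total and by gene length, so a change in a few abundant genes moves the others, and a gene with a low value rests on few reads.

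Relative depth was estimated from the ratio between libraries of the lowest values, under 0.5 FPKM, of the same gene: the ratio shared by the most genes within 0.01 on the log2 scale was taken. Between 559 and 599 genes entered for each library after wild-type replicate 1, and between 33 and 77 of them met at the chosen ratio, against a median of 2 or 3 at other ratios. The precision of a low value is therefore known only through the spread between replicates.

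Each column was assigned to its sample by its label. Gene names and the order of neighbours come from the RefSeq annotation of TAIR10.1, which matched 22053 of the 22107 nuclear loci. As the authors' build is not named, no coordinates are printed. Plastid and mitochondrial loci have no name in that annotation under their identifiers and are given by identifier.

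Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate changes of genes with low values. Genes with a mean FPKM of at least 1 over the 6 libraries (18064 genes) were tested between mutant and wild type with limma 3.58.1 in R 4.3.3, with a mean trend in the moderated variance, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene in the text is from limma. NCBP, CBP20 and ABH1 were also compared by an exact permutation test, which cannot go under 0.1 with 3 against 3 libraries. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists with at least 5 tested members, and again with an estimated correlation and with fry. Of the 23 lists, 3 passed with the preset correlation, 0 with an estimated correlation and 6 with fry, while 4 and 1 had an unadjusted camera p under 0.05 with the preset and the estimated correlation. With 3 libraries per group the test with an estimated correlation has little power, so failing it does not show that a list is unchanged. The limma step was tested on simulated data for this comparison with all 18064 genes: of 100 genes changed 1.5-fold and 100 changed 2-fold, 86% and 97% were recovered, with 11 false calls among the unchanged genes. The simulated changes were set on the log2(FPKM + 1) scale, and the noise used the fitted variances and was independent between genes. Correlated genes and library effects were therefore not covered.

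The 25 gene lists (407 entries, 396 distinct loci, 389 of them in the table) covered cap binding, RNA metabolism, hormones, stress, light, clock, nutrition and markers of root, flower and seed. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took NCBP, CBP20 and CBP80, the 10 largest changes in each direction among genes past the threshold whose groups do not overlap, and up to 4 members of each list with the smallest p past the threshold, or the member with the smallest p where none passed. Other members are named to complete a count of their list. A named gene that this rule took from a list is not reported here. The lists of low-oxygen genes, of thalianol and marneral genes, and of dawn- and dusk-phased genes in the closing section were written after the results were seen.

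The alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, rescaling to the same sum (TPM), median-ratio scaling, quantile normalization, leaving out organelle genes, no mean trend, robust moderation, array weights, a replicate block, leaving out each library in turn and a 2-fold minimum. After organelle genes were left out, the libraries were also rescaled to the same sum. Leaving out genes listed at 0 in any library was added after the data were seen. The positions of changed genes were tested with windows of 50 neighbouring tested genes against 10000 random placements (2000 for each alternative). Medians of the low-oxygen, root marker, thalianol and marneral, and dawn- and dusk-phased clock lists carry 95% bootstrap intervals over members from 10000 draws. These steps ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. No sample was left out of the comparison.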

Results

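RNA from whole 2-week-old Arabidopsis thaliana seedlings was sequenced in 6 libraries, 3 from wild-type plants and 3 from plants labelled as an NCBP mutant. NCBP is the symbol of AT5G18110 in the TAIR10.1 annotation, a cap-binding protein of the eIF4E family, and the comparison asks which transcripts differ between such plants and the wild type. The deposited values were FPKM, fragments scaled to gene length and library total, for 22426 loci. No library totals were given, so the absolute depth is unknown, but ratios between the lowest values of a gene placed the depth of the libraries, relative to wild-type replicate 1, at 1.098 and 1.173 for wild-type replicates 2 and 3 and at 1.244, 1.161 and 1.310 for mutant replicates 1, 2 and 3. Between 17824 and 18052 loci reached an FPKM of 1 in each library. Nothing in the labels states that the replicates came from separate sowings, so the p-values measure only the spread between these libraries, which may be technical.

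The NCBP transcript was lower in the mutant libraries but not absent. NCBP (AT5G18110) had 98.6 ± 1.61 FPKM in wild type and 57.6 ± 1.73 FPKM in the mutant (SD, n = 3 each), which is 58.5% of the wild-type level. The log2 fold change was -0.76 (SE 0.05), with a limma adjusted p of 0.000146. The 3 mutant libraries, at 57.9, 59.2 and 55.8 FPKM, all lay below the 3 wild-type libraries, at 97.4, 100.4 and 97.9 FPKM. The subunits of the nuclear cap-binding complex did not pass the threshold. CBP20 (AT5G44200) had 32.1 ± 2.06 FPKM in wild type and 28.8 ± 0.652 FPKM in the mutant, with an adjusted p of 0.128. ABH1 (AT2G13540), which encodes CBP80, had 13.2 ± 0.466 and 14.1 ± 0.92 FPKM, with an adjusted p of 0.459. In 2-sided exact permutation tests the p was 0.1 for NCBP, 0.1 for CBP20 and 0.2 for ABH1, and 0.1 is the smallest p that 3 against 3 libraries allow. The labels do not say which allele the mutant carried, and an FPKM for the whole gene cannot show which part of a transcript was made. In TAIR10.1 the exons of NCBP share 142 bases, 12.7% of their length, with CSD3 on the opposite strand, and because the strand of the library protocol was not stated, reads from that part cannot be assigned to either gene.

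**Figure D1:**
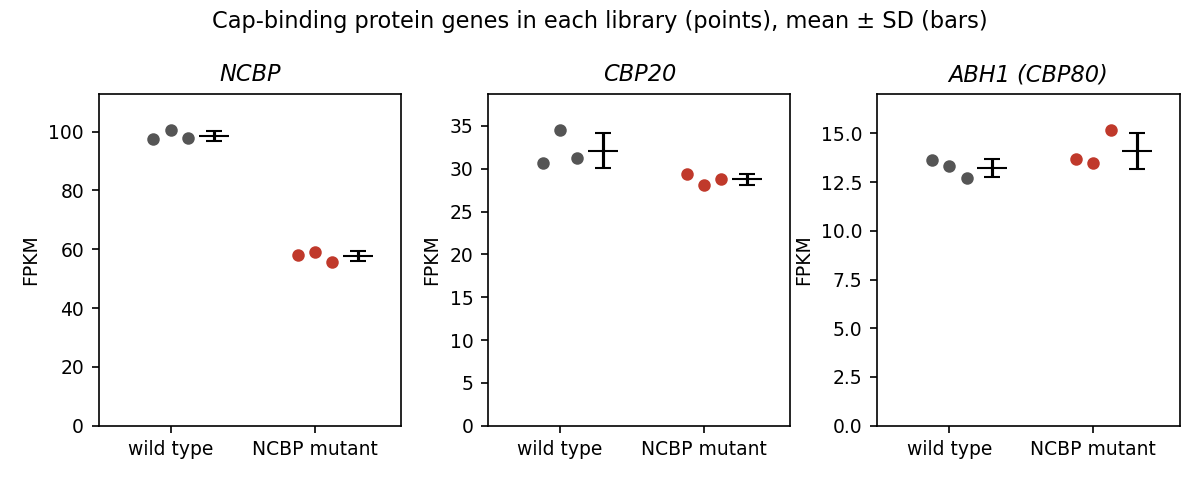
FPKM of NCBP, CBP20 and ABH1 (vertical axes, from 0) in each of the 3 wild-type libraries (grey points) and 3 mutant libraries (red points); black bars give the mean ± SD. NCBP lies between 97.4 and 100.4 FPKM in wild type and between 55.8 and 59.2 FPKM in the mutant, while the difference of CBP20 and of ABH1 did not pass the threshold.

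Of 18064 genes tested, 2657 (14.7%) changed in the mutant at an adjusted p under 0.05, 1133 of them higher and 1524 lower. Most changes were small. A change of at least 2-fold was seen in 106 genes, 61 higher and 45 lower. The values of the groups did not overlap for 6417 genes (35.5%), where chance gives 10% with 3 against 3 libraries. The balance of directions depended on scaling: after rescaling each library to the same sum, as in TPM, 1286 genes were higher and 1100 lower, which moved the higher share from 42.6% to 53.9%, and with organelle genes left out as well 1305 were higher and 1107 lower. The count of changed genes was 1680 without wild-type replicate 3, 1321 without mutant replicate 1 and 1391 without mutant replicate 2.

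The largest fitted rise of a gene with values above 0 in each library was that of HEI10 (AT1G53490), known for its part in meiotic crossover formation, from 0.663 ± 0.109 to 15.01 ± 0.889 FPKM (log2 fold change 3.27, SE 0.10, adjusted p 3.00e-06). Its neighbour MRD1 (AT1G53480) rose from 0.0565 ± 0.0978 to 3.29 ± 0.216 FPKM. The exons of these genes overlap on opposite strands in TAIR10.1, over 40.9% of the exonic length of HEI10 and 73.8% of that of MRD1. Reads from the shared part cannot be told apart without strand, and MRD1 also shares 83.1% of its exonic length with AT1G07887 on the opposite strand. COR15B (AT2G42530), a cold-regulated chloroplast protein, rose from 10.3 ± 0.357 to 69.0 ± 18.5 FPKM (log2 fold change 2.60, SE 0.17), and 29.5% of its exonic length is shared with AT2G42520 on the other strand. PR1 (AT2G14610), a marker of the salicylic acid response, rose from 0.32 ± 0.328 to 6.77 ± 5.02 FPKM (adjusted p 0.0137). PCR1 (AT1G14880) rose from 0.903 ± 0.27 to 6.88 ± 2.81 FPKM, and the loci AT5G10040, AT2G17850 and AT3G29970 rose from 0.33, 2.69 and 0.383 FPKM to 7.45, 12.5 and 3.71 FPKM. AT5G10040 was listed at 0 in 1 wild-type library, and AT3G29970 and MRD1 were each listed at 0 in 2. The plastid locus ATCG00640 was listed at 0 in the 3 wild-type libraries and at 16.4, 8.46 and 7.96 FPKM in mutant replicates 1, 2 and 3. TOM7-2 (AT1G64220), a subunit of the mitochondrial outer membrane translocase, was likewise listed at 0 in wild type and at 17.1, 3.03 and 14.3 FPKM in the mutant libraries, and a listed 0 can be a failed estimate. With pseudocounts of 5 and 0.1 in place of 1 the log2 fold change was 1.82 and 4.32 for HEI10, 1.21 and 4.49 for AT5G10040 and 0.68 and 3.93 for AT3G29970. Without mutant replicate 1 the adjusted p of AT3G29970 was 0.0513 and that of PR1 was 0.051, and with robust moderation that of PR1 was 0.0561 and that of AT2G17850 was 0.0623, with ranges of 0.00805 to 0.0513, 0.002 to 0.0561 and 0.00295 to 0.0623 over their alternatives.

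Among the largest falls, FLC (AT5G10140), a repressor of flowering, went from 13.5 ± 2.11 to 2.503 ± 0.356 FPKM (log2 fold change -2.05, SE 0.13, adjusted p 0.000146). Its relative MAF5 (AT5G65080) fell from 8.62 ± 0.903 to 1.64 ± 0.665 FPKM. AT2G16005, annotated with a lipid recognition domain, fell from 40.6 to 7.67 FPKM (log2 fold change -2.28). HIS1-3 (AT2G18050), a linker histone, fell from 46.8 ± 8.70 to 12.7 ± 0.834 FPKM, and the F-box family gene AT1G73120 from 78.6 ± 15.7 to 24.0 ± 1.48 FPKM. GRP3S (AT2G05380), a glycine-rich protein, fell from 951 ± 139.9 to 317 ± 38.4 FPKM, and another glycine-rich protein gene, AT3G02670, from 2.53 ± 0.387 to 0.292 ± 0.17 FPKM. LEA18 (AT2G35300), a late embryogenesis abundant protein, fell from 13.0 ± 3.49 to 4.14 ± 2.90 FPKM (adjusted p 0.0204). A pair of loci added by the authors under their own names, new genes 364 and 74, fell by 2.44 and 1.89 on the log2 scale, and their positions were not given in the sources used here. An antisense transcript annotated as AT5G01675 covers 68.1% of the exonic length of FLC, so the FLC value may include its reads, and AT3G02670 shares 32.9% of its exonic length with AT3G02673 on the opposite strand. With a pseudocount of 5 the log2 fold change of FLC was -1.30 and that of new gene 364 (Arabidopsis_newGene_364) was -1.39. The call of LEA18 was lost without wild-type replicate 1 (adjusted p 0.0576) or 2 (0.0612) and without mutant replicate 1 (0.0535) or 3 (0.0592) and with robust moderation (0.0889), with a range of 0.00407 to 0.0889 over its alternatives.

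Flowering-time genes moved in both directions. Of 22 listed members, 15 were tested, of which 4 rose, 4 fell and 7 did not pass. Adjusted over the list alone, 7 rose and 4 fell. The members that fell were the repressors FLC, MAF5, MAF4 and FLM (MAF1). MAF4 (AT5G65070) went from 9.09 ± 2.03 to 2.86 ± 0.926 FPKM (log2 fold change -1.39, SE 0.19, adjusted p 0.00364), and FLM changed by only -0.19 (adjusted p 0.0483). MAF2, MAF3 and SVP, further repressors of this kind, did not pass, at log2 fold changes of 0.07, -0.18 and 0.11. The members that rose were SOC1 (AGL20), a promoter of flowering, at 27.1 and 38.8 FPKM in wild type and mutant, GI, SPL3 and SPL9, of which SPL9 (AT2G42200) went from 7.57 ± 0.395 to 10.8 ± 0.675 FPKM (adjusted p 0.0072). FT, TSF, CO, SPL5, AP1, LFY and FUL lay under the FPKM filter and were not tested. As a set the list did not pass (camera adjusted p 0.627), with a median log2 fold change of 0.11, a mean of -0.19 and a camera direction of up. An antisense transcript annotated as AT2G33815 covers 97.3% of the exonic length of SPL3. With a pseudocount of 5 the log2 fold change of MAF4 was -0.84. The call of SPL3 was lost without wild-type replicate 1 (adjusted p 0.0509) or 3 (0.0541) and without mutant replicate 1 (0.0515) or 2 (0.066), with a range of 0.0127 to 0.066 over its alternatives.

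Circadian clock genes also split. All 21 members of the list were tested, and 6 rose, 7 fell and 8 did not pass. Adjusted over the list alone, 8 rose and 7 fell. The members that fell were LHY, CCA1, RVE8, RVE1, LNK1, LNK2 and ZTL, most of them known to peak in the morning. LHY (AT1G01060) fell from 6.71 ± 1.11 to 2.00 ± 0.346 FPKM (log2 fold change -1.36, SE 0.13, adjusted p 0.000844), CCA1 (AT2G46830) from 40.5 ± 1.499 to 26.9 ± 1.295 FPKM, RVE8 (AT3G09600) from 15.5 ± 0.747 to 8.67 ± 0.245 FPKM and LNK2 (AT3G54500) from 196 ± 4.01 to 138 ± 5.96 FPKM. The members that rose were PRR5, ELF4, LUX, GI, FKF1 and GRP7, known to peak later in the day, with log2 fold changes of 0.70, 0.71, 0.51, 0.34, 0.75 and 0.43. TOC1 had 15.01 FPKM in wild type and 17.0 FPKM in the mutant, with an adjusted p of 0.261, and PRR9, PRR7, PRR3, ELF3, RVE6, GRP8 and BOA did not pass either. The set as a whole did not pass (camera adjusted p 0.769). With a pseudocount of 5 the log2 fold change of LHY was -0.74. The labels give a photoperiod of 16 hours of light and 8 hours of dark but no hour of harvest, so the hour may differ between the groups.

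**Figure D2:**
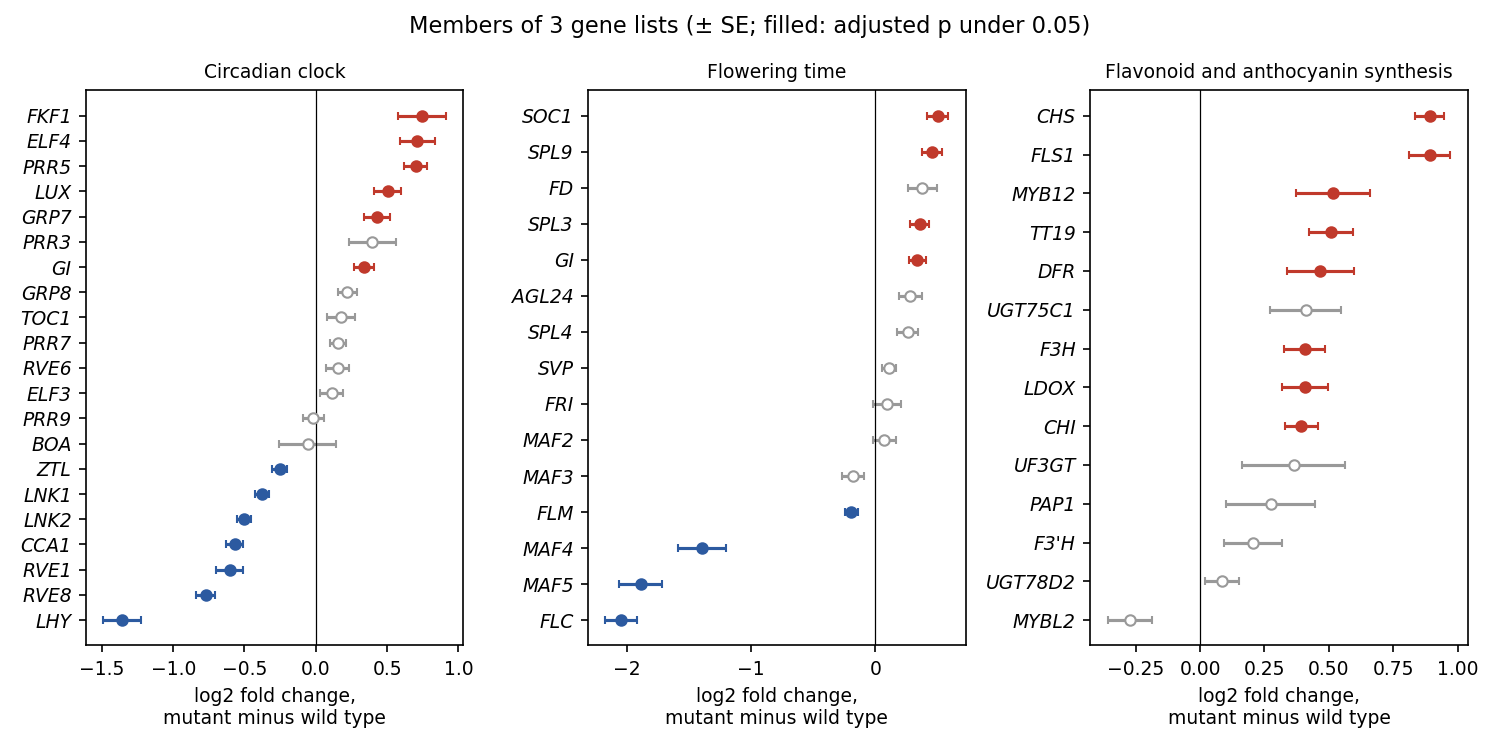
Log2 fold change, mutant minus wild type, on the log2(FPKM + 1) scale (horizontal axes) of each tested member of the clock, flowering-time and flavonoid lists; points are the fitted values and bars their SE, filled red or blue where the adjusted p is under 0.05 and open grey otherwise. LHY, RVE8 and CCA1 lie left of 0 and FKF1, ELF4 and PRR5 right of it, while 8 of the 14 flavonoid members are filled on the right and none on the left.

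Of 16 listed flavonoid and anthocyanin genes, 14 were tested, of which 8 rose, 0 fell and 6 did not pass. Adjusted over the list alone, 9 rose and 1, MYBL2, fell. TT4 (AT5G13930), which encodes chalcone synthase, the entry enzyme of the pathway, rose from 40.4 ± 1.47 to 75.7 ± 3.80 FPKM (log2 fold change 0.89, SE 0.06, adjusted p 0.000146). FLS1 (AT5G08640), flavonol synthase, rose from 11.1 ± 0.985 to 21.4 ± 1.34 FPKM, TT5 (AT3G55120), chalcone isomerase, from 15.3 ± 0.562 to 20.4 ± 1.15 FPKM, and GSTF12 (TT19, AT5G17220), an anthocyanin transport factor that shares 9.85% of its exonic length with PSY on the opposite strand, from 5.85 ± 0.469 to 8.73 ± 0.542 FPKM. F3H, DFR, LDOX and the regulator MYB12 rose as well, while the regulators PAP1 and MYBL2 did not pass, at log2 fold changes of 0.27 and -0.27. The list differed from other genes by camera with a preset correlation (adjusted p 1.37e-05). It did not with an estimated correlation (0.0205, against the preset 0.01), where the unadjusted camera p was 0.00919 and the adjusted p was 0.211.

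Of 11 tested genes of leaf senescence and sugar starvation, 5 fell, 1 rose and 5 did not pass, and adjusted over the list alone 9 fell and 1 rose. SEN1 (AT4G35770), a dark-inducible gene, fell from 118 ± 27.6 to 55.0 ± 10.2 FPKM (log2 fold change -1.07, SE 0.18, adjusted p 0.00668). ASN1 (AT3G47340), an asparagine synthetase induced by darkness, fell from 58.0 ± 12.8 to 33.3 ± 4.96 FPKM, and NAC6 (ORE1, AT5G39610), a regulator of leaf ageing, from 9.21 ± 1.12 to 5.96 ± 0.479 FPKM. SAG29 and NAP fell too. SAG13 (AT2G29350) moved the other way, from 0.924 ± 0.216 to 3.61 ± 2.18 FPKM (adjusted p 0.0274). The camera adjusted p was 0.00402 with the preset correlation of 0.01 and 0.593 with an estimated correlation. The estimated correlation was 0.152, and a preset below the true correlation makes the camera p too small. The call of SAG13 was lost without wild-type replicates 1 (adjusted p 0.0784), 2 (0.0651) or 3 (0.0551) and without mutant replicate 1 (0.0586) and with no filter (0.0529), with a range of 0.0193 to 0.0784 over its alternatives.

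Of 18 tested salicylic acid and immune genes, 3 rose, 1 fell and 14 did not pass, and the counts adjusted over the list alone were also 3 and 1. PR1 rose as above, PAD3 (AT3G26830), the last enzyme of camalexin synthesis, rose from 1.88 ± 0.393 to 3.79 ± 0.607 FPKM (log2 fold change 0.73, SE 0.14, adjusted p 0.0126), and WRKY70 (AT3G56400) from 7.44 ± 0.974 to 10.96 ± 1.27 FPKM. EDS16 (ICS1, AT1G74710), the isochorismate synthase that makes the precursor of salicylic acid, fell from 7.78 ± 0.248 to 5.78 ± 0.268 FPKM. By camera the adjusted p was 0.0254 with the preset correlation of 0.01 and 0.715 with an estimated correlation. The estimated correlation was 0.176, above the preset, so the camera p with the preset may be too small. With fry the list did not pass (adjusted p 0.148). The list lost its call at a mean FPKM of at least 5 (adjusted p 0.341), without wild-type replicates 1 (0.0592) or 2 (0.062) and without mutant replicate 3 (0.11), with a range of 0.00427 to 0.341 over the alternatives that kept the preset correlation. With a pseudocount of 5 the log2 fold change of PAD3 was 0.35. The calls of PR1 and EDS16 were lost without mutant replicate 1 (adjusted p 0.051 and 0.0551) and that of WRKY70 without mutant replicate 3 (0.0556), with ranges of 0.002 to 0.0561, 0.0101 to 0.0551 and 0.0139 to 0.0556.

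Of 24 tested genes of the abscisic acid and drought response, 8 rose, 3 fell and 13 did not pass, and adjusted over the list alone 9 rose and 4 fell. LTI78 (RD29A, AT5G52310) rose from 12.2 ± 0.891 to 25.1 ± 0.197 FPKM (log2 fold change 0.99, SE 0.07, adjusted p 0.000146), COR15A (AT2G42540) from 33.6 ± 3.84 to 66.5 ± 9.95 FPKM and ERD10 (AT1G20450) from 58.0 ± 2.63 to 84.1 ± 1.85 FPKM. KIN1, KIN2, P5CS1 and ADH1 rose, as did COR15B. RAB18, the phosphatase HAB1 and the transcription factor ABF4 fell, at log2 fold changes of -0.30, -0.47 and -0.22. The list as a set did not pass by camera (adjusted p 0.148) but passed as higher with fry (adjusted p 0.005765), which does not compare a list with other genes. Of 5 tested cold-response regulators, 2 rose, 0 fell and 3 did not pass, the same numbers adjusted over the list alone. GolS3 (AT1G09350) rose from 0.604 ± 0.182 to 2.08 ± 0.313 FPKM and DREB1A (CBF3, AT4G25480) from 3.77 ± 0.45 to 5.84 ± 0.645 FPKM, while the camera adjusted p was 0.29. With fry the cold list passed as higher (adjusted p 0.0379). COR15A and COR15B, and KIN1 and KIN2, are similar copies, and how the authors assigned reads that fit both is not given in the sources used here. The call of DREB1A was lost without mutant replicate 2 (adjusted p 0.0625, range 0.0143 to 0.0625).

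Of 16 tested jasmonate and wound genes, 3 rose, 2 fell and 11 did not pass, and adjusted over the list alone 4 rose and 2 fell. AOC1 (AT3G25760), an allene oxide cyclase of jasmonate synthesis, fell from 60.3 ± 4.91 to 33.3 ± 3.95 FPKM (log2 fold change -0.84, SE 0.09, adjusted p 0.00146), and AOS fell by 0.21 on the log2 scale. LOX2 (AT3G45140) rose from 52.6 ± 1.17 to 75.6 ± 9.15 FPKM, ORA59 (AT1G06160) from 2.24 ± 0.718 to 5.29 ± 1.28 FPKM and VSP2 (AT5G24770) from 102 ± 20.1 to 139 ± 9.33 FPKM. AOC2 and VSP1 did not pass, at log2 fold changes of -0.01 and -0.39. How the authors assigned reads that fit AOC1 and AOC2, or VSP1 and VSP2, is not given in the sources used here. The list as a set did not pass by camera (adjusted p 0.694). The call of VSP2 was lost without each library except wild-type replicate 2, at adjusted p of 0.082 and 0.0571 without wild-type replicates 1 and 3 and of 0.0711, 0.111 and 0.112 without mutant replicates 1, 2 and 3, and with no filter (0.0791), no mean trend (0.0823), robust moderation (0.0562) and a replicate block (0.0558) (range 0.0166 to 0.112).

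Genes of cap binding and of the initiation factor 4F complex mostly did not pass beyond NCBP. Of 10 members tested, 1 rose, 2 fell and 7 did not pass, the same numbers adjusted over the list alone. eIFiso4G2 (AT2G24050) rose from 13.1 ± 0.3 to 15.9 ± 1.04 FPKM (adjusted p 0.0359) and EIF4G (AT3G60240) fell from 27.0 ± 1.61 to 22.7 ± 1.14 FPKM (adjusted p 0.0431), while EIF4E and LSP1, the gene of eIF(iso)4E, did not pass. By camera the list had an adjusted p of 0.751, with a median log2 fold change of 0.06, a mean of -0.06 and a camera direction of down. With fry the list, which includes NCBP itself, passed as lower (adjusted p 0.0383). The call of eIFiso4G2 was lost without any of the 6 libraries, at adjusted p between 0.0601 and 0.119, and with no filter (0.0511), no mean trend (0.0525) and a replicate block (0.0706), with a range of 0.0267 to 0.119. That of EIF4G was lost without wild-type replicates 1 (0.117) and 3 (0.114) and mutant replicates 1 (0.0878), 2 (0.082) and 3 (0.118) and also under the rescaling to the same sum (0.0906), median-ratio scaling (0.0572), quantile normalization (0.0716), no filter (0.0574), organelle genes left out (0.0892), no mean trend (0.0737) and a replicate block (0.0785), with a range of 0.0332 to 0.118.

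Of 13 genes of mRNA decay and small RNA production, 1 fell, 0 rose and 12 did not pass, the same adjusted over the list alone. Among 26 tested microRNA targets, 3 rose, 2 fell and 21 did not pass, and adjusted over the list alone 4 rose and 4 fell. SPL9, SPL3 and TCP4 rose, SPL3 from 9.06 ± 0.675 to 11.9 ± 0.523 FPKM. PHO2 (AT2G33770), a ubiquitin-conjugating enzyme of phosphate balance, fell from 50.1 ± 4.16 to 39.2 ± 1.03 FPKM and the laccase gene IRX12 (AT2G38080) from 10.3 ± 0.626 to 7.91 ± 0.55 FPKM. Of 23 cytosolic ribosomal protein genes, 1 rose, 1 fell and 21 did not pass, the same adjusted over the list alone. RPL3B (AT1G61580) fell from 20.1 ± 1.47 to 14.2 ± 1.24 FPKM and AT3G09200, which encodes RPP0B, rose from 300.2 ± 18.1 to 362 ± 12.6 FPKM. By camera these lists had adjusted p values of 0.694, 0.931 and 0.446, and the microRNA targets had a median of -0.02 and a mean of 0.01 on the log2 scale with a camera direction of up. The calls of IRX12 and AT3G09200 were lost without some libraries, for IRX12 without wild-type replicate 3 (adjusted p 0.074) and mutant replicates 1 (0.0766) and 2 (0.0503), and for AT3G09200 without mutant replicates 1 (0.0708) and 2 (0.0569) and with no mean trend (0.05002), with ranges of 0.018 to 0.0766 and 0.00325 to 0.0708.

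Among nuclear photosynthesis genes only RCA passed the threshold. Of 22 tested, 21 did not pass, 0 rose and 1 fell, and adjusted over the list alone 0 rose and 0 fell, while 2 had an unadjusted limma p under 0.05. RCA (AT2G39730), Rubisco activase, fell from 5949 ± 375 to 4932 ± 116 FPKM (adjusted p 0.047). The list as a set did not pass by camera (adjusted p 0.446). Without wild-type replicate 1 the list was called as higher (adjusted p 0.00298, range 0.00298 to 0.985 over alternatives with the preset correlation), while with all libraries the adjusted p was 0.944 with an estimated correlation. The call of RCA was lost without wild-type replicate 2 (0.0686) and without mutant replicates 1 (0.148), 2 (0.142) and 3 (0.138), with no filter (0.166), with median-ratio scaling (0.06) and with a replicate block (0.142), with a range of 0.0167 to 0.166.

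Among 9 reactive oxygen genes, CAT1 (AT1G20630), a catalase, rose from 44.0 ± 3.08 to 53.8 ± 2.71 FPKM and CAT2 (AT4G35090) fell from 1011 ± 74.6 to 797 ± 11.98 FPKM, 7 did not pass, and adjusted over the list alone 2 rose and 2 fell. Among 10 heat shock and protein folding genes, HSP70 (AT3G12580) fell from 17.57 ± 1.31 to 13.7 ± 0.449 FPKM and MBF1C (AT3G24500) from 20.5 ± 1.33 to 15.5 ± 1.88 FPKM, although 14.6% of its exonic length is shared with AT3G04685 on the opposite strand, 0 rose and 8 did not pass, and adjusted over the list alone 3 fell and 0 rose. Among 8 phosphate starvation genes, SQD2 (AT5G01220), a sulfolipid synthase, fell from 37.3 ± 1.92 to 28.3 ± 2.06 FPKM and PHO2 fell as above, 6 did not pass, and 2 fell and 0 rose adjusted over the list alone. Among 15 iron genes, FER4 (AT2G40300), a ferritin, rose from 43.3 ± 6.77 to 55.9 ± 1.64 FPKM and 14 did not pass, with 0 past the threshold adjusted over the list alone and 1 at an unadjusted limma p under 0.05. The camera adjusted p values were 0.693, 0.344, 0.694 and 0.931, and the iron list had a median of 0.01 and a mean of -0.07 with a camera direction of up. The call of CAT1 was lost without wild-type replicates 2 (adjusted p 0.0561) and 3 (0.0529) and mutant replicates 2 (0.0653) and 3 (0.0709) and with no mean trend (0.0549), that of CAT2 without mutant replicate 2 (0.0503) and that of HSP70 without wild-type replicate 3 (0.0516) and mutant replicate 1 (0.0603), with ranges of 0.0168 to 0.0709, 0.00763 to 0.0503 and 0.0115 to 0.0603. The call of MBF1C was lost without wild-type replicates 1 (0.056), 2 (0.076) and 3 (0.0546) and mutant replicates 1 (0.0519) and 2 (0.0663) and with no mean trend (0.0522) or a replicate block (0.0609), and that of FER4 without wild-type replicates 2 (0.0913) and 3 (0.0917) and mutant replicates 1 (0.0949), 2 (0.105) and 3 (0.0686) and with no filter (0.0634) or no mean trend (0.0718), with ranges of 0.0191 to 0.076 and 0.00648 to 0.105.

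Of 18 glucosinolate genes, 2 rose, 1 fell and 15 did not pass, and adjusted over the list alone 3 rose and 1 fell. CYP79B3 (AT2G22330), which makes the indole glucosinolate precursor, fell from 46.8 ± 3.93 to 28.8 ± 2.13 FPKM (log2 fold change -0.68, SE 0.08, adjusted p 0.00158), IMS2 (MAM3, AT5G23020) rose from 11.2 ± 0.9 to 17.0 ± 1.19 FPKM and SUR1 (AT2G20610) from 43.0 ± 3.44 to 51.6 ± 2.497 FPKM. Of 11 auxin response genes, 2 fell, 0 rose and 9 did not pass, and 3 fell adjusted over the list alone. WES1 (GH3.5, AT4G27260), an enzyme that conjugates auxin, fell from 18.6 ± 0.597 to 12.2 ± 0.784 FPKM and IAA29 (AT4G32280) from 9.06 ± 0.663 to 5.35 ± 1.07 FPKM. Of 11 cytokinin genes, RR16 (AT2G40670) rose from 1.59 ± 0.166 to 3.44 ± 0.945 FPKM and 10 did not pass, the same adjusted over the list alone. Of 9 ethylene genes, EBF1 (AT2G25490) rose from 46.0 ± 1.80 to 55.5 ± 1.28 FPKM and 8 did not pass, with 2 higher and 1 lower adjusted over the list alone. The camera adjusted p values of the 4 lists were 0.344, 0.307, 0.992 and 0.446, and the cytokinin list had a positive median and mean of 0.01 and 0.03 but a camera direction of down. With fry the auxin list passed as lower (adjusted p 0.004275). The call of SUR1 was lost without each library except wild-type replicate 1, at adjusted p of 0.0946 and 0.108 without wild-type replicates 2 and 3 and of 0.0632, 0.1 and 0.108 without mutant replicates 1, 2 and 3, and with no filter (0.0548), no mean trend (0.0769) and a replicate block (0.0796) (range 0.0171 to 0.108). That of RR16 was lost without wild-type replicates 1 (0.0545) and 3 (0.0547) and mutant replicates 1 (0.064) and 3 (0.057), and that of EBF1 without mutant replicate 1 (0.0503), with ranges of 0.0122 to 0.064 and 0.0084 to 0.0503.

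Markers of other organs mostly did not pass. Of 20 root markers, 1 rose, 1 fell and 18 did not pass, the same adjusted over the list alone (camera adjusted p 0.694). HKT1 (AT4G10310), a sodium transporter, fell from 2.95 ± 0.297 to 1.19 ± 0.293 FPKM, and NRT2:1 (AT1G08090), a nitrate transporter, rose from 0.932 ± 0.41 to 2.42 ± 0.746 FPKM. Of 7 flower markers, only PI and SEP3 reached the filter and neither passed over all genes, SEP3 (AT1G24260) at 1.92 ± 0.277 and 2.91 ± 0.502 FPKM (adjusted p 0.0712); adjusted over the list alone, 1 rose and 1 fell. None of the 9 seed storage markers reached the filter. Of 7 cell division genes, none passed at an adjusted p under 0.05 by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p 0.446). CYCB1;1 (AT4G37490), a mitotic cyclin, had 39.1, 9.48 and 5.32 FPKM in wild-type replicates 1, 2 and 3 and 25.3, 50.5 and 22.4 FPKM in the mutant libraries. Without wild-type replicate 1 its adjusted p was 0.0163 (range 0.0163 to 0.505), and the call of NRT2:1 was lost without wild-type replicates 1 (0.0678) and 2 (0.0783) and mutant replicates 1 (0.084) and 2 (0.111) and with no filter (0.0507), quantile normalization (0.0514) and a replicate block (0.0792), with a range of 0.0255 to 0.111.

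The libraries of a group resembled each other more than those of the other group. Pearson correlations of log2(FPKM + 1) across genes ranged from 0.989 to 0.991 within groups and from 0.98 to 0.984 between groups, and genes are not independent replicates. The first principal component held 44.0% of the variance and separated the groups, with scores of -17.9, -19.0 and -17.2 in wild type and 20.4, 16.5 and 17.2 in the mutant. The 10 most abundant genes held between 12.5% and 13.8% of the summed FPKM, and plastid loci held at most 0.083%.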

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

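Leaving out the filter was planned, while the count of its calls among genes under the filter was a test chosen only after the result was seen. The groups hold 3 samples each, too few for a test of single samples that stand apart from their group.

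The main comparison in the report leaves out 4362 genes with a mean FPKM under 1. When the filter was left out, 105 of these genes passed the threshold, 70 of them higher in the mutant and 35 lower, which drew attention because the main comparison does not use these genes. AT5G05300 was listed at 0 in the 3 wild-type libraries and at 0.943, 1.03 and 0.947 FPKM in the mutant libraries. AGL8 (FUL, AT5G60910), a floral regulator, had 0.356, 0.589 and 0.511 FPKM in wild type and 1.46, 1.03 and 1.70 FPKM in the mutant. The metallothionein gene AtMT4b (AT2G23240) was at 1.59, 0.593 and 0.829 FPKM in wild type and listed at 0 in the mutant, and EM1 (AT3G51810), a late embryogenesis abundant protein, was at 0.402, 0.265 and 0.291 FPKM in wild type and listed at 0, 0.0489 and 0 in the mutant. These genes were picked after their values were seen. Values this low rest on few reads. The estimated relative depth was 1, 1.098 and 1.173 in wild-type replicates 1, 2 and 3 and 1.244, 1.161 and 1.310 in mutant replicates 1, 2 and 3. Loci listed at 0 numbered 1345, 1275 and 1204 in wild type and 1167, 1213 and 1127 in the mutant, in the same order. Whether this difference in depth accounts for the excess of higher genes was not tested, nor was any other explanation.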

How the results depend on the processing

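Leaving out genes listed at 0 was chosen only after the result was seen. The fall of NCBP kept its direction and call under its 19 alternatives, at log2 fold changes from -0.78 to -0.73 and adjusted p from 6.43e-05 to 0.00225. No named gene was reversed, nor were the 3 lists past the threshold. Lists that did not pass turned direction: the iron list with a replicate block and without wild-type replicates 1 or 2, the microRNA targets without wild-type replicate 2, the phosphate list without wild-type replicate 3, the cytokinin list with fry and without wild-type replicates 2 or 3 or mutant replicates 1 or 2, and the clock list with fry. Higher genes outnumbered lower ones under TPM rescaling and with organelle genes left out, which included the same rescaling and so is not a separate check. With a 2-fold minimum, by construction, the counts fell from 2657, 1133 higher and 1524 lower, to 106, 61 and 45. Leaving out a library, which leaves fewer samples, gave 1321 to 1997 changed genes, 579 to 987 higher and 720 to 1107 lower; without mutant replicate 1, 1270 of the 1321 were also called with all libraries. Under the other alternatives 1980 to 2802 genes changed. A block for the replicate number gave 1991, although the labels do not say whether the numbers pair the samples. The lists past the threshold were 3 with the preset correlation, 0 with an estimated correlation and 6 with fry, which does not compare a list with other genes. With fry the flavonoid, abscisic acid and cold lists passed as higher, and the auxin, senescence and cap-binding lists as lower. The salicylic acid list did not pass with fry (adjusted p 0.148). The replicate structure, mean correlation within minus between groups, was 0.00726, and 0.00873 with a pseudocount of 0.1, 0.00601 with 5, 0.00434 with no filter and 0.0096 at a mean FPKM of at least 5; the cause was not tested. Of 70 other named genes that were called, 47 kept the call without each library in turn and 23 lost it at least once, between 9 and 19 per library, and 14 lost it under another alternative. Depth limits the genes with low values, and as it is unknown, no floor can be given.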

Other observations

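All tests in this part were chosen only after the result was seen, except the other splits of the samples and the positions of changed genes.

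Genes of the thalianol and marneral clusters, which make root triterpenes, were lower. Of 5 tested, 4 fell and 0 rose, with a median log2 fold change of -1.14 (bootstrap 95% interval -1.38 to -0.55), in a list written after the values were seen. The interval runs over members and does not measure the spread between libraries. MRN1 (AT5G42600), marneral synthase, fell from 2.37 ± 0.976 to 0.258 ± 0.133 FPKM, CYP705A5 (AT5G47990) from 8.93 ± 1.44 to 3.13 ± 0.192 FPKM, CYP708A2 (AT5G48000) from 9.29 ± 1.302 to 3.69 ± 0.759 FPKM and THAS1 (AT5G48010), thalianol synthase, from 4.95 ± 0.92 to 2.21 ± 0.412 FPKM.

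The 6 libraries can be split into groups of 3 in 10 ways, and 1 of the 10, the real split, gave as many as 2657 changed genes. The highest count of the other splits was 1. Those splits mix libraries of both groups, so a difference between the groups adds to their spread and lowers their counts. Their counts therefore do not show how many calls chance alone would give. With 10 splits the share cannot go under 0.1, so a share under 0.05 is out of reach.

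Clock genes moved apart by the time of day at which most are known to peak. Of 7 dawn-phased genes, 6 fell (median log2 fold change -0.57, bootstrap 95% interval -0.77 to -0.38), and of 11 dusk-phased genes, 6 rose (median 0.40, interval 0.18 to 0.70). But these lists were written after the values were seen, and the intervals run over members and do not measure the spread between libraries. They leave out ZTL, which fell past the threshold, and RVE6 and PRR7, at 0.15 and 0.16 without passing. Outputs outside the clock list leaned the same way. Of 8 dawn-phased outputs, 0 were above 0, and COL1, COL2, CDF2 and LNK4 passed as lower. Of 3 dusk-phased outputs, 3 were above 0 without passing. But the difference of medians, 0.53, had an exact permutation p of 0.0788 over 165 arrangements. The arrangements shuffle genes and not libraries, so this p does not measure the spread between libraries. The mutant libraries may therefore be at another circadian phase, which these few genes leave open. A different hour of harvest cannot be told apart from an effect of genotype, because 0 of the 6 samples have a labelled hour.

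Low-oxygen response genes were higher in the mutant: of 22 tested, 15 rose and 0 fell, with a median log2 fold change of 0.75 (bootstrap 95% interval 0.53 to 1.07), in a list written after the values were seen. Without the members that passed with a change of at least 2-fold, 14 remained, of which 7 rose, 0 fell and 7 did not pass. Their median was 0.54 (interval 0.22 to 0.73). These 14 come from the same list, so they do not remove that selection and are not independent support. HB1 (AT2G16060), a hemoglobin, rose from 22.3 ± 6.06 to 62.6 ± 14.3 FPKM, ADH1 (AT1G77120), alcohol dehydrogenase, from 41.5 ± 16.6 to 108 ± 29.6 FPKM, SUS4 (AT3G43190), sucrose synthase, from 8.04 ± 2.53 to 22.3 ± 6.05 FPKM and PDC1 (AT4G33070), pyruvate decarboxylase, from 15.8 ± 6.01 to 39.2 ± 8.19 FPKM. A larger root share in the mutant libraries is argued against by the 20 root markers, whose median log2 fold change was 0.0598 (interval -0.06 to 0.21). These intervals run over members and do not measure the spread between libraries. The mean log2 level of the root markers was 3.017, 2.971 and 3.061 in wild-type replicates 1, 2 and 3. It was 3.015, 3.007 and 3.1 in mutant replicates 1, 2 and 3. The mean log2 level of the low-oxygen genes was 3.655, 4.063 and 4.324 in wild-type replicates 1, 2 and 3. In mutant replicates 1, 2 and 3 that level was 4.747, 4.994 and 4.531. The lowest mutant library exceeded the highest wild-type library by only 0.21, and the exact permutation p of 0.1 is the smallest possible. Oxygen or handling that differed from sample to sample may therefore still account for the difference. An effect of the genotype on the low-oxygen response stays open beside it.

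APRL7 (AT5G18120), the divergent neighbour of NCBP, fell more than NCBP did, from 31.7 ± 0.997 to 14.1 ± 1.06 FPKM (log2 fold change -1.12, SE 0.07, adjusted p 0.000146), and the next gene, AT5G18130, fell by 0.67 on the log2 scale, while CSD3 on the other side rose by 0.39. The exons of NCBP and APRL7 share 0 bases in TAIR10.1, which argues against reads shared between overlapping gene models of that annotation. The annotation behind the FPKM is not given in the sources used here, so an overlap in the authors' models stays open. A stretch of another genetic background around the mutated gene may contribute and cannot be told apart from an effect of the mutation: 3 of the 20 tested flanking genes changed, CSD3, AT5G18130 and GDH1, against a mean of 2.94 in stretches of 20 genes (share with as many 0.581). An effect of an insertion or edit at NCBP on its neighbours was not tested, since the allele is not given in the sources used here.

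The fullest window of 50 neighbouring tested genes, from AT3G28715 to AT3G29590, held 17 changed genes, and the median of the fullest windows in 10000 random placements was also 17 (permutation p 0.707). Among 101 placed genes changed at least 2-fold, 6 pairs of direct neighbours moved the same way, against a mean of 0.295 in random draws (permutation p 1e-04, the smallest these draws can give). The pairs were MRD1 and HEI10, PDF1.3 and PDF1.2b, PCC1 and AT3G22235, AT4G10265 and AT4G10270, CYP705A5 and CYP708A2, and MAF4 and MAF5. MRD1 and HEI10 overlap. With neighbours of the same product text left out, 5 pairs remained against a mean of 0.287 (permutation p 1e-04, again the smallest possible), but product text misses related copies such as MAF4 and MAF5.

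The share of genes called was 15.7% in the shortest, 15.9% in the middle and 12.4% in the longest group of genes by exonic length, with a Spearman correlation of -0.0258 between length and log2 fold change across 17814 genes, which are not independent replicates.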
